A study of Mus musculus with 2 samples.

How the data were processed

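Libraries were made from TUBO cells on plastic by column extraction with DNase treatment and a stranded mRNA kit, per the labels' protocols. The deposited table holds raw counts per gene symbol, which the authors made before deposit, for 31017 genes in 2 columns. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.9a, featureCounts, R 4.1.1, Cell Ranger 3.0.0 and the build mm10, with no role or order. The annotation release, the strand setting of the counting and the handling of reads with several matches are not given in the sources used here. Reads shared by similar genes, overlapping genes or antisense genes can therefore be split, lost or doubled in these counts, and levels of such genes are uncertain.

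Each column was assigned to its sample by the replicate number in the labels. The totals were 35453278 counts in replicate 1 and 34098259 in replicate 2. A floor of 3 counts, the upper limit that a count of 0 allows, was 0.0842 and 0.0885 CPM. Intervals on shares are 95% Wilson intervals. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

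Counts were scaled to CPM with TMM factors of 1.005 and 0.995 in edgeR 4.0.16 (R 4.3.3). CPM is not divided by gene length, so levels of different genes are compared as counts. Length-divided values were computed as an alternative from exonic lengths. Gene symbols were matched to GENCODE M21 (GRCm38), where 98.3% of the genes in the table had a single match. To find shared sequence, every 50-base window of the transcripts of each named gene was looked up in the transcripts of all other genes; genomic sequence outside transcripts was not searched.

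Before the data were examined, 46 gene lists holding 697 genes and 6 pairs of lists were fixed. After these, the rule for named genes and the alternative settings were fixed, levels and shifts of lists were looked at in an exploratory pass, before the calculations given here took their final form. Mx2 and Cxcl11 were on the lists and not in the table. Differences between lists are differences of median log2(CPM + 1) in each library, with mean and SD over both. The rule for named genes, fixed at the same time, took the 10 most abundant genes off the mitochondrial genome, the 4 highest and 2 lowest members of each list (all members of lists of up to 6 genes), a fixed set of receptors, cancer genes and markers, and the 5 genes with the largest ratio between libraries in each direction among called genes with a mean of 10 CPM or more. Members of the mitochondrial list and genes of the dispersion-based test that fall outside the rule were chosen after their values were seen, as was the choice of Cdh1, Krt18 and Vim for fold ratios.

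Genes were kept for tests between libraries with filterByExpr, leaving 13336 genes with 99.95% of the counts. The common dispersion came from estimateDisp with an intercept alone. Each gene was tested with a two-sided exact binomial test given the effective library sizes, adjusted by Benjamini-Hochberg. The median log2 ratio of each list was set against 10000 random lists matched on level. On simulated libraries with the real means and sizes, a coefficient of variation of 0.03 was recovered as 0.0303. In libraries simulated with counting noise alone the test called 0 genes. In separate ones with a coefficient of variation of 0.03 and changed genes added, it called 84.5% of those changed 1.5-fold and 86.6% of those changed 2-fold. The unchanged genes called at 0.03 were not counted, so the 0 is no error rate for the real libraries. Of 200 lists simulated with no shift and independent noise for each gene, 12 fell outside the central 95%.

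Alternatives planned beforehand were total counts, DESeq2 1.42.0 size factors and dispersions, upper-quartile factors, other detection minimums and filters, other pseudocounts, length-divided values, means of lists, subsets of list members and each library left out in turn. The removal of the length trend and of Gm26917 and Gm42418 from the totals, and 20 further random draws of the matched lists, were added after seeing the data. So were the count of lists outside the central 95% and the tolerances that decide whether such values moved.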

Results

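RNA was sequenced from TUBO cells, a mouse mammary cancer line that was derived from a tumour of a mouse carrying the rat Her2/neu transgene. The cells were untreated and grown as flat cultures on plastic. The labels give 1 group with 2 libraries, so the level of each gene is the measurement and no condition is compared with another. Replicate 1 held 35453278 counts and replicate 2 held 34098259 counts over 31017 genes. Levels are counts scaled to the library total (CPM), given as mean ± SD over the 2 libraries (n = 2). A count of 0 allows a level of up to 0.0842 CPM in replicate 1 and 0.0885 CPM in replicate 2, covering counting error only. A gene is called detected at 1 CPM or more in both libraries.

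In all, 11692 genes were detected, 2315 of them at 100 CPM or more in both libraries. Of the detected genes, 11006 were protein-coding, 313 were antisense genes and 254 were lincRNA genes. The strand setting of the counting is not given, so detection of antisense genes is uncertain. No count was found for 12710 genes. Apart from the mitochondrial genome, the 10 most abundant genes were Gm26917, Gm42418, Malat1, Actb, Eef1a1, Pkm, Spp1, Abhd2, Lcn2 and Actg1. Among them were the cytoskeletal actins Actb (6187 ± 419 CPM) and Actg1 (2584 ± 84.2 CPM), the glycolytic enzyme Pkm (3223 ± 134 CPM), the secreted phosphoprotein Spp1 (2933 ± 54.0 CPM) and the iron-siderophore carrier Lcn2 (2803 ± 24.1 CPM). Gm26917 (chromosome 17, 39843013 to 39846341, GRCm38) and Gm42418 (chromosome 17, 39846958 to 39848788) are annotated as lincRNA genes. RefSeq lists Gm42418 as a synonym of Rn18s-rs5, a ribosomal RNA-related pseudogene, and 94.9% of its 50-base windows were also found in transcripts of other genes. The span that RefSeq gives for Rn18s-rs5 (39846354 to 39848202) starts just past the end of Gm26917. Whether the counts of Gm26917 also come from ribosomal RNA was not tested. These 2 genes took 9.84% of the counts of replicate 1 (95% Wilson interval 9.83% to 9.85%) and 11.1% of those of replicate 2 (11.1% to 11.1%).

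Epithelial genes were abundant and most mesenchymal genes were near or below the floor. Of 31 measured epithelial genes 30 were detected, led by the keratin Krt18 (1217 ± 15.2 CPM), the junction protein Jup (1013 ± 58.0 CPM), the adhesion molecule Epcam (898 ± 4.77 CPM) and Krt7 (788 ± 31.1 CPM). The epithelial cadherin Cdh1 stood at 774 ± 31.2 CPM. Krt19 was the exception, with 2 counts in replicate 1 and 0 in replicate 2. Of 27 mesenchymal genes 8 were detected, among them the intermediate filament gene Vim (111 ± 7.78 CPM), the fibronectin gene Fn1 (31.9 ± 1.14 CPM), the gelatinase gene Mmp2 (25.7 ± 1.01 CPM) and the repressor gene Zeb2 (14.6 ± 0.392 CPM), while 10 had no count, including Snai2, Dcn and Lum. Cdh1 was 6.85 and 7.14 times as abundant as Vim in replicates 1 and 2, and Krt18 10.6 and 11.5 times. Divided by gene length, the Krt18 ratio was 36.4 ± 2.10. The median log2(CPM + 1) of the epithelial list exceeded that of the mesenchymal list by 7.69 ± 0.05, far more than the spread between libraries. The epithelial median lay above all of 10000 random lists of as many genes, and the mesenchymal median above 52.7% of them in replicate 1 and 57.1% in replicate 2. These lists were drawn from all 31017 genes, of which 12710 had no count. The housekeeping median lay above all of its random lists too, so this percentile reflects expression and not an epithelial identity. The difference was 3.90 over detected members only. With 2 libraries an exact sign test cannot go below p = 0.5, so no p-value is given for any such difference.

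**Figure D1:**
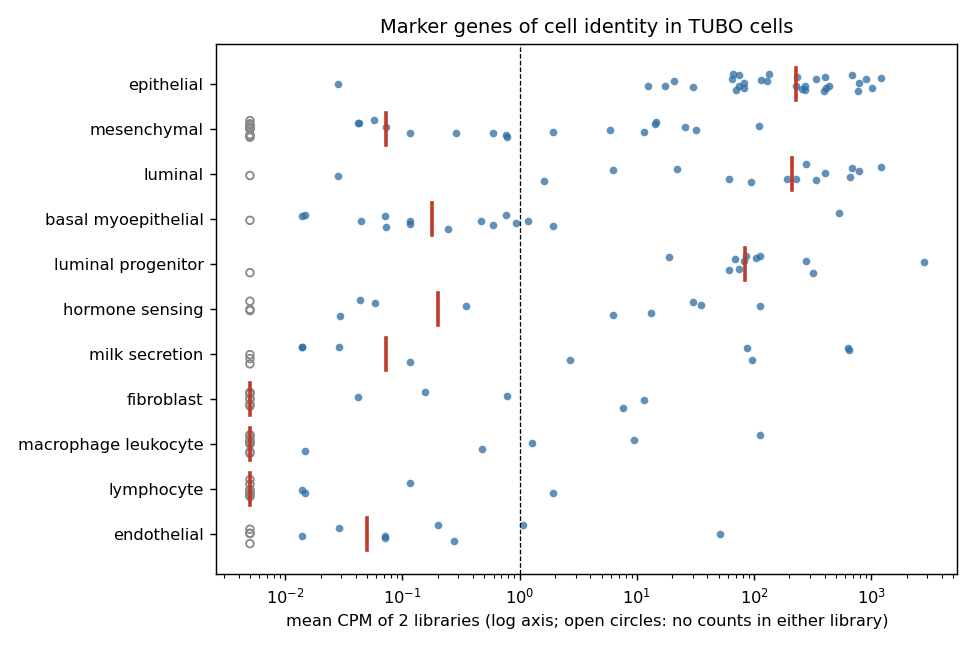
Mean CPM over the 2 libraries (log axis) of the members of 11 marker lists, 1 point per gene. Red bars are list medians, open circles are genes with no count and the dashed line marks 1 CPM; epithelial, luminal and luminal progenitor genes lie mostly above the line.

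The mammary lineage genes were of luminal type, with luminal progenitor genes high and hormone-sensing genes low. Of 16 luminal genes 14 were detected, including Krt8 (684 ± 18.8 CPM) and the transcription factor gene Tfap2c (663 ± 17.7 CPM), and Spdef had no count. Of 16 basal or myoepithelial genes 2 were at 1 CPM or more in both libraries. These were Sox10, a transcription factor gene of neural crest and mammary progenitor cells, at 532 ± 15.6 CPM (chromosome 15, 79154908 to 79165240), and the Notch ligand gene Jag2 at 1.92 ± 0.576 CPM. The basal keratin genes Krt5 (3 and 2 counts) and Krt14 (0 and 3 counts) were at the floor. Of 12 luminal progenitor genes 11 were detected, with Lcn2 followed by the Notch target Hey1 (316 ± 3.59 CPM), the transcription factor gene Elf5 (275 ± 2.73 CPM) and Cd14 (113 ± 1.03 CPM). Of 12 hormone-sensing genes 5 were detected, led by the prolactin receptor gene Prlr (113 ± 1.63 CPM).

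The luminal median exceeded the basal median by 7.47 ± 0.08 on the log2 scale, and the hormone-sensing median minus the luminal progenitor median was -6.15 ± 0.08. Over detected members only, these differences were 2.68 and -1.45, and with a pseudocount of 5 CPM they were 5.36 and -4.09. Esr1, the oestrogen receptor alpha gene, had 0 and 2 counts, while Pgr and Pparg had none. Of 12 nuclear receptor genes 7 were detected, with the retinoic acid receptor gene Rarg (104 ± 1.93 CPM) and the glucocorticoid receptor gene Nr3c1 (67.5 ± 2.89 CPM) highest. Milk genes were mixed, with 5 of 12 detected. Mfge8 (649.7 ± 27.3 CPM) and the kappa-casein gene Csn3 (629 ± 15.9 CPM) were abundant, and the beta-casein gene Csn2 and Glycam1 had no count.

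Among the ErbB receptor genes, Erbb2 (chromosome 11, 98412470 to 98437716) was the most abundant at 687 ± 12.2 CPM, followed by Erbb3 at 349 ± 7.91 CPM and Egfr at 14.3 ± 0.847 CPM. Erbb4 had no count in either library. Erbb2 was 48.2 ± 2.01 times as abundant as Egfr, a log2(CPM + 1) difference of 5.49 ± 0.05. Divided by gene length, the ratio was 104.8 ± 4.37 and the difference 6.44. The ErbB ligand list had 8 of 11 members detected, led by Tgfa (128 ± 3.86 CPM), Hbegf (64.6 ± 0.433 CPM) and Areg (30.4 ± 0.233 CPM). Ereg and Nrg3 had no count. The table has no separate row for the rat transgene, so the Erbb2 value may hold reads from both genes.

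Of 22 other receptor tyrosine kinase genes 13 were detected, led by the hepatocyte growth factor receptor gene Met (237 ± 3.41 CPM), Fgfr1 (212 ± 0.737 CPM), the ephrin receptor gene Ephb4 (155 ± 2.77 CPM) and the collagen receptor gene Ddr1 (153 ± 5.88 CPM). Alk had no count. In the list of cancer genes 23 of 25 were detected. The cyclin D1 gene Ccnd1 was highest at 1601 ± 44.6 CPM, and the kinase gene Akt1 (430.4 ± 10.8 CPM), Nf1 (350.2 ± 26.6 CPM), Trp53 (149.8 ± 3.01 CPM) and Myc (88.5 ± 0.976 CPM) were all detected. The tumour suppressor gene Cdkn2a had no count, and Mycl had 1 count in replicate 1.

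**Figure D2:**
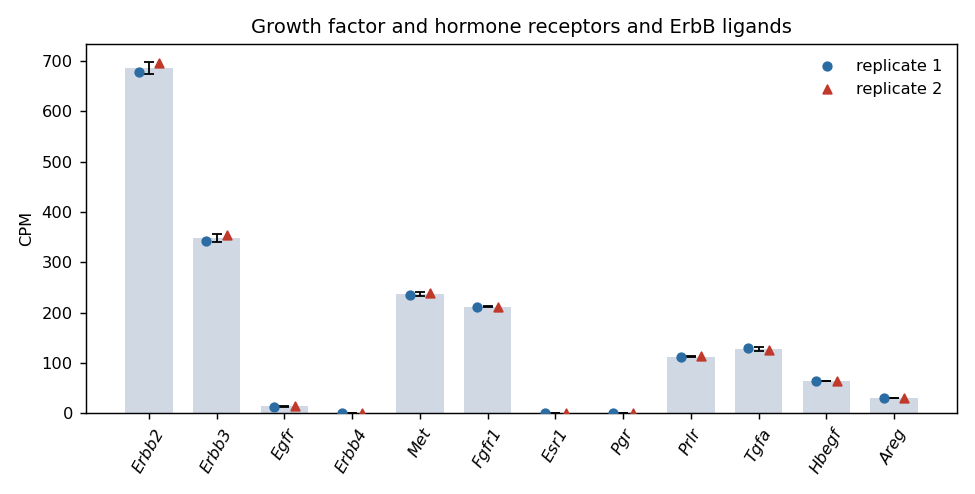
CPM of growth factor and hormone receptor genes and ErbB ligand genes, with bars at the mean, points for each library and error bars of 1 SD (n = 2). Erbb2 is the highest at 687 CPM, and Erbb4 and Pgr have no count.

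Integrin and basement membrane genes were abundant. Of 19 integrin genes 15 were detected, with Itgb1 at 761 ± 14.4 CPM, Itga6 at 409.6 ± 3.67 CPM and Itga3 at 399 ± 13.5 CPM, all subunits of laminin receptors. Itga4 and Itga5 had no count. Of 20 basement membrane genes 14 were detected, led by the laminin gene Lama5 (548 ± 25.7 CPM) and the collagen gene Col4a1 (429 ± 12.4 CPM). Of 22 genes of matrix proteases and their inhibitors 14 were detected, with the cathepsin genes Ctsd (635 ± 7.71 CPM) and Ctsb (618 ± 6.65 CPM) highest and Mmp13 and Timp1 without a count. The mechanosensing list had 18 of 19 members detected, including the nuclear lamin gene Lmna (445 ± 15.7 CPM), the ion channel gene Piezo1 (241 ± 2.02 CPM) and Yap1 (199.8 ± 1.80 CPM), and Piezo2 had no count. Of 22 YAP target genes 16 were detected, led by Myof (511 ± 11.3 CPM) and the tissue factor gene F3 (317 ± 2.67 CPM), and Nuak2 and Rbms3 had no count.

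Every gene of both cell cycle lists was detected, 20 of 20 for S phase and 22 of 22 for G2 and M phase. The ribonucleotide reductase genes Rrm2 (376 ± 16.4 CPM) and Rrm1 (329.7 ± 10.1 CPM) and the sliding clamp gene Pcna (296 ± 0.541 CPM) led the S-phase list. The proliferation marker Mki67 (701 ± 51.1 CPM) and the topoisomerase gene Top2a (634 ± 12.9 CPM) led the mitotic list. Of 10 genes of inhibitors of the cyclin-dependent kinases and related pocket proteins 7 were detected, including Cdkn1b (168 ± 1.61 CPM) and Cdkn1a (139 ± 4.41 CPM), and Cdkn2b had no count. The S-phase median exceeded the inhibitor median by 1.64 ± 0.03 on the log2 scale, by 0.97 when values were divided by gene length and by 2.52 when list means were taken in place of medians. Of 19 p53 target genes 16 were detected, led by Plk2 (292 ± 3.68 CPM) and Ccng1 (167 ± 0.782 CPM), and the pro-apoptotic gene Pmaip1 had no count.

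Glycolytic genes stood above nuclear genes of oxidative phosphorylation in CPM. All 20 glycolytic genes were detected, with Pkm followed by Gapdh (1772 ± 7.08 CPM) and Aldoa (1300.4 ± 10.6 CPM). All 31 nuclear genes of oxidative phosphorylation were detected as well, led by the ATP synthase genes Atp5b (1159 ± 40.0 CPM) and Atp5a1 (786 ± 12.2 CPM). The medians differed by 1.76 ± 0.04 on the log2 scale, but by only 0.32 when values were divided by gene length. Lipid synthesis genes were abundant, with the desaturase genes Scd2 (1865 ± 59.9 CPM) and Scd1 (1199 ± 20.8 CPM) leading 13 of 14 detected fatty acid genes. Of 21 cholesterol genes 20 were detected, with the synthase gene Hmgcs1 highest at 427 ± 14.7 CPM.

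The 13 protein-coding genes of the mitochondrial genome took 1.64 ± 0.0463% of the counts and fell into 2 ranges. Of these genes 7 were abundant, from mt-Nd6 at 444 ± 27.3 CPM upward, with mt-Co1 at 7184 ± 146 CPM, mt-Nd1 at 3114 ± 137 CPM and mt-Cytb at 2314 ± 137 CPM. The other 6, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, lay between 0.115 and 1.33 CPM. Over these 6 genes the median share of 50-base windows also found in transcripts of other genes was 99.2%, against 7.61% over the 7 abundant genes. Of the abundant genes, mt-Nd4 (62.2%) and mt-Co1 (51.1%) also shared most of their windows. The levels of the low genes, mt-Nd4 and mt-Co1 are therefore uncertain, and so is the share of counts taken by the mitochondrial genes.

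**Figure D3:**
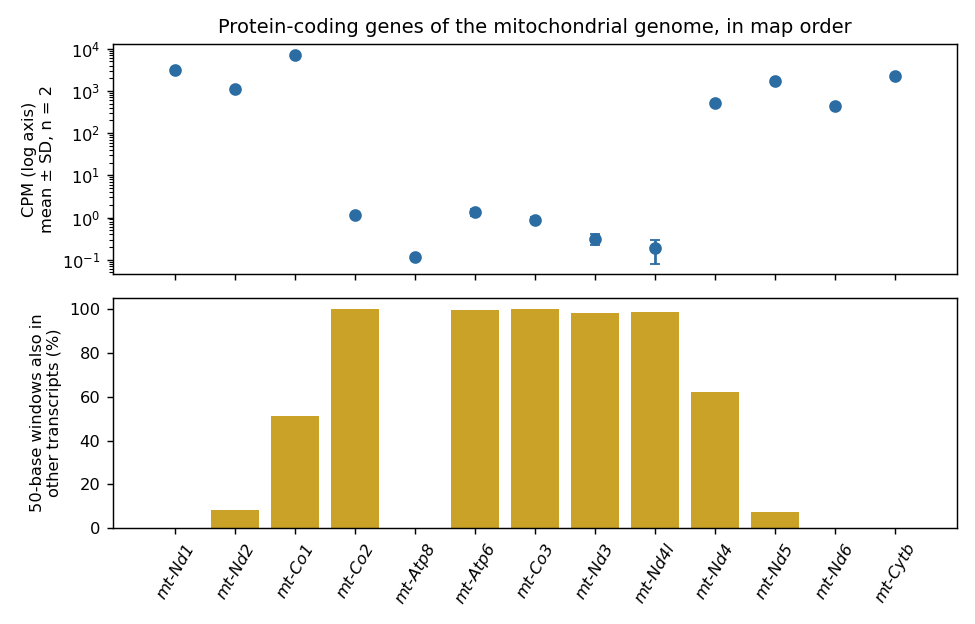
Protein-coding genes of the mitochondrial genome in map order, with CPM (log axis, mean ± SD, n = 2) above and the percentage of 50-base windows also found in transcripts of other genes below. The 6 low genes lie next to each other, and mt-Atp8 is the low gene with no shared window.

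Antigen presentation genes of class I were detected and most of class II were not. Of 14 class I genes 11 were detected. Calr (622 ± 9.83 CPM) and Pdia3 (557 ± 9.42 CPM) were highest, and both are also on the unfolded protein list. The light chain gene B2m (285 ± 3.89 CPM) and the loading factor gene Tapbp (143 ± 5.08 CPM) followed. The immunoproteasome genes Psmb8 (6 and 5 counts) and Psmb9 (7 and 6 counts) were below 1 CPM. Of 10 class II genes H2-DMa (6.62 ± 0.192 CPM) and the class II activator gene Ciita (104 and 84 counts) were detected, and 7, including H2-Aa, had no count. The medians differed by 5.20 ± 0.03 on the log2 scale, a size that depends on the pseudocount because the class II median was 0. It was 8.49 with a pseudocount of 0.1 CPM and 3.03 with 5 CPM, and 3.69 over detected members only. TUBO cells descend from BALB/c mice, which differ from the reference strain at this locus, so levels of its polymorphic genes are uncertain.

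Interferon-response genes were low, with 8 of 24 measured genes detected and the sensor gene Ddx58 highest at 82.6 ± 0.405 CPM. Among 20 checkpoint and immune ligand genes 11 were detected, led by Cd24a (229 ± 2.91 CPM), Cd200 (159 ± 6.25 CPM) and the phagocytosis inhibitor gene Cd47 (96.4 ± 3.04 CPM). Cd274, the gene of PD-L1, was at 0.645 ± 0.120 CPM. Of 31 measured cytokine and chemokine genes 18 were detected. Spp1 (chromosome 5, 104435118 to 104441050) was followed by Lif (212 ± 0.392 CPM), the granulocyte colony-stimulating factor gene Csf3 (187 ± 2.59 CPM) and Tgfb3 (177 ± 13.4 CPM), and Il1b had no count.

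Stress genes were detected broadly. All 16 genes of the amino acid response, all 16 of the unfolded protein response and all 15 of the hypoxia list were detected, as were 10 of 12 heat shock genes and 18 of 19 immediate early genes. The amino acid transporter gene Slc7a5 (422 ± 24.2 CPM), the chaperone genes Hsp90b1 (731 ± 6.44 CPM) and Hsp90ab1 (2148 ± 93.2 CPM), the oxygen sensor gene Egln3 (223 ± 2.84 CPM) and Ier3 (324 ± 0.742 CPM) were highest in their lists. The stress-induced transcription factor genes Ddit3 (11.7 ± 0.453 CPM) and Atf3 (8.73 ± 0.0426 CPM) were the lowest of the amino acid list.

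Markers of other cell types were mostly at the floor. No adipocyte, erythroid or muscle gene of the 8, 6 and 7 measured was detected. Among 12 fibroblast genes Postn (11.5 ± 0.877 CPM) and Pdgfra (7.64 ± 1.08 CPM) were detected, and among 12 endothelial genes Flt1 (51.1 ± 0.679 CPM) and Egfl7 (1.06 ± 0.0846 CPM). Of 14 macrophage and leukocyte genes Cd14, Cd68 (9.43 ± 0.116 CPM) and Fcer1g (1.27 ± 0.167 CPM) were detected, and of 12 lymphocyte genes Lck alone (1.92 ± 0.543 CPM). Of 8 neural and glial genes 2 were detected, with Mbp highest at 47.2 ± 2.27 CPM. All 13 housekeeping genes were detected. Xist, the RNA of the inactive X chromosome, was at 1659.7 ± 219 CPM, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had no count.

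The libraries agreed closely in level but not within counting noise. Of called genes with a mean of 10 CPM or more, the 5 with the largest log2 ratio of replicate 2 to replicate 1 were Gm26803 (0.44), Ahnak (0.40), Snhg6 (0.40), Sem1 (0.39) and Syne2 (0.39). The 5 with the lowest were Tigar (-0.40), Plek2 (-0.35), Tfap4 (-0.35), Gm10093 (-0.33) and 1600014C10Rik (-0.33), of which Gm10093 shares 84.4% of its 50-base windows with other transcripts. The abundant noncoding RNAs Malat1 (0.25) and Xist (0.27) were also higher in replicate 2. Across the 13336 genes kept by the expression filter, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.9987 and Spearman's rho was 0.9985. The common dispersion gave a coefficient of variation of 3.12%, and the chi-square statistic of the counts was 6.40 times its degrees of freedom. Very abundant genes weigh heavily in that statistic, such as Gm26917 with 3139168 and 3410282 counts (log2 ratio 0.19). The libraries were treated as separate samples.

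An exact binomial test of each gene, which compares these 2 libraries and covers counting error only, called 1084 genes at a Benjamini-Hochberg adjusted p under 0.05. Of these, 489 were higher and 595 lower in replicate 2, and 33 differed by 1.5-fold or more. The split depended on the scaling, since 45.1% of calls were higher in replicate 2 with TMM factors, 28.9% (374 against 921) with total counts and 37.7% (434 against 716) with DESeq2 size factors. When the dispersion of the same libraries was allowed for, edgeR's exact test called 19 genes, all of them higher in replicate 2. The labels do not say that the replicates were separate cultures, so the differences may be technical. The binomial p-values set each difference against counting error alone. Those of edgeR's exact test use a dispersion estimated from these same differences, so neither test measures the spread between independent cultures.

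Gene lists differed little between the libraries. Of 38 lists with at least 3 kept members, 7 had a median log2 ratio outside the central 95% of 10000 random lists matched on level. By chance 1.9 are expected, for genes drawn independently. Members of a list can vary together, so 1.9 may not be the number expected between replicate libraries. The count of lists outside depends on the random draw and was 7 to 8 over 20 other draws, with heat shock genes as the list that varied. Hypoxia genes (median 0.11) and mitochondrial genes (0.12) were higher in replicate 2, with 3 of 15 and 6 of 10 kept members called, and the same numbers when adjusted over the list alone. Nuclear genes of oxidative phosphorylation (0.02) had 3 members called higher and 2 lower, both over all genes and when adjusted over the list alone, and their median moved inside the central 95% (percentile 93.44) once the trend on gene length was removed. S-phase genes (-0.07) were lower in replicate 2, with 9 of 20 members called over all genes and 11 when adjusted over the list alone. Cholesterol genes (-0.06) had 6 members called lower and 0 higher over all genes, and 11 and 2 when adjusted over the list alone. Fatty acid genes (-0.06) had 7 called lower and 2 higher, and 7 and 3 when adjusted over the list alone, and moved inside likewise (percentile 3.24). Interferon-response genes (-0.17) had no member called either way, and their median was 0.00999 over members with a mean of 10 CPM or more. Calls of members do not by themselves mark a shifted list. Of all kept genes, 8.13% were called, and lists inside the central 95% had calls too. The epithelial list (percentile 23.115) had 1 of 30 kept members called higher and 9 lower. The luminal list (percentile 11.95) had 6 of 14 called lower.

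**Figure D4:**
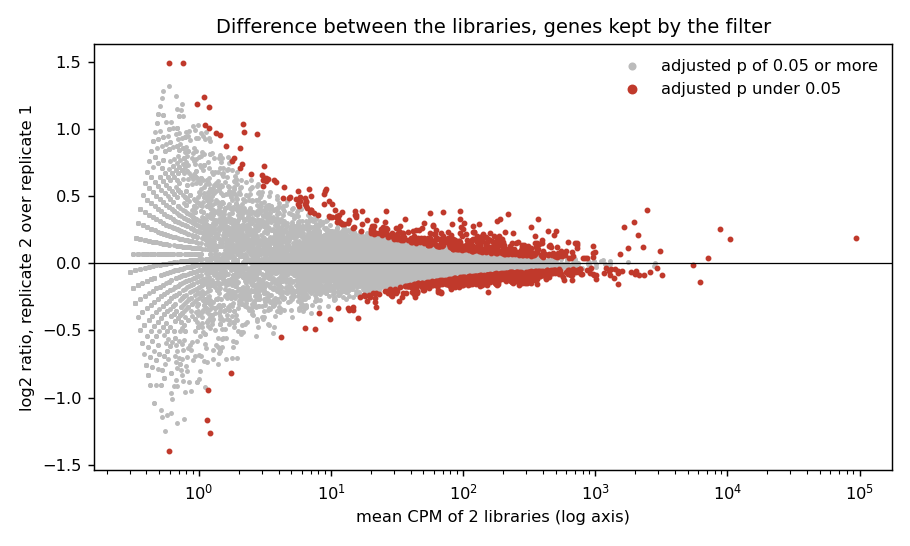
Log2 ratio of replicate 2 to replicate 1 against mean CPM (log axis) for the genes kept by the filter, with the 1084 genes called by the exact binomial test in red. Most called genes lie close to 0, and 33 differ by 1.5-fold or more.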

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

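Removing the length trend, leaving Gm26917 and Gm42418 out of the totals and repeating the random draws were chosen after seeing the data; all other settings were planned. Every difference between lists kept its direction under every alternative run, and total counts moved each by less than the SD. With a pseudocount of 0.1 CPM the differences were 10.14 for epithelial minus mesenchymal, 9.59 for luminal minus basal, -8.32 for hormone-sensing minus luminal progenitor, 8.49 for class I minus class II and 5.58 for Erbb2 minus Egfr. With 5 CPM they were 5.50, 5.36, -4.09, 3.03 and 5.17, with 1.72 for glycolysis minus oxidative phosphorylation and 1.56 for S phase minus inhibitors. Length-divided values gave, in the same order, 7.14, 7.17, -6.27, 5.33, 6.44, 0.32 and 0.97. Means in place of medians gave 5.89, 5.31, -4.38 and 4.28 for the first 4 pairs, 1.32 for glycolysis and 2.52 for S phase. Members at 1 CPM or more gave 3.90, 2.68, -1.45 and 3.69 for the first 4 pairs and 1.45 for S phase. Without the most abundant member of each list the differences were 7.34 for epithelial, -6.30 for hormone-sensing, 4.96 for class I, 1.25 for glycolysis and 1.42 for S phase. Each of these settings changes the scale or the members by construction.

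The square root of the median gene-wise dispersion of DESeq2 was 0.0001, the method's lower limit, where 65.7% of the kept genes lay, so it is no estimate to set against edgeR's 0.0312. edgeR's exact test with the common dispersion called 19 genes in place of 1084, since it adds the spread shared by all genes to counting noise; 736 genes had an unadjusted p under 0.05. The interferon-response shift turned from -0.17 to 0.00999 over members with a mean of 10 CPM or more, a setting that leaves fewer members. Leaving out each library in turn cannot show instability with 2 libraries, as the shift is fixed by the SD. The count of 7 lists outside the central 95% was 7 with total counts, 6 over genes with a mean of 10 CPM or more, where the interferon list was lost, and 6 with the length trend removed. That removal took oxidative phosphorylation (percentile 97.975 to 93.44) and fatty acid genes (1.04 to 3.24) inside and glycolysis (94.22 to 98.14) outside. Over 20 other random draws the count was 7 to 8. Heat shock (percentile 2.525) lay close to the bound and fell outside in 5 of the 20 draws, and oxidative phosphorylation fell outside in all 20 (97.825 to 98.34). No paired analysis was possible because there is only 1 group. Leaving Gm26917 and Gm42418 out of the totals raised levels by 11.7%. Depth limits genes near 3 counts, where neither absence nor a difference can be shown.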

Other observations

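The cell cycle inhibitor genes Cdkn2a and Cdkn2b had no count in either library, while Mtap, which lies beside them on the mouse chromosome and was chosen after its values were seen, was at 40.3 ± 2.22 CPM. Among the genes called by edgeR's exact test, also chosen after their values were seen, were the long noncoding RNAs Kcnq1ot1 (log2 ratio of replicate 2 to replicate 1 of 0.38) and Neat1 (0.31) and the cytolinker genes Macf1 (0.33) and Dst (0.33).

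The patterns weighed were picked after the levels had been seen. The tests chosen only after their result or closely related values were seen are both tests of short genes, of gene length as the whole cause and of gene length among the genes past the dispersion-based test. The last of these was at first read as favouring length, from the count of genes alone; a condition on the median ratio was added once its value was seen, and the test is now read as undecided. The share of calls left after removing a trend was at first a ratio of counts of calls (79.3% for length, 92.4% for GC) and was replaced, after these values were seen, by the share of the same genes still called. The test of short mitochondrial genes was at first read against that cause and its rule was tightened, since it rested on 1 gene. The design, with 1 group, names no biological difference between the libraries. No biological cause of their differences was therefore tested beside the technical explanations, and such a cause is not excluded.

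Reads shared with near-identical copies elsewhere may account for 5 of the 6 mitochondrial genes near the floor. The median share of windows found in transcripts of other genes was 99.2% over the 6 and 7.61% over the 7 abundant genes. The genes mt-Nd4 and mt-Co1 were abundant with most of their windows shared (62.2% and 51.1%). Their other windows were not shared, so reads could still be counted there, and their abundance does not decide the question. Loss of short genes stays open, because 3 of the low genes are longer than mt-Nd6 (519 bases) but the other 6 abundant genes are all longer than every low gene, and 18 nuclear protein-coding genes no longer than the longest low gene (784 bases) reached 100 CPM, under the 20 set as the bound against it. The low gene mt-Atp8 had no shared window in transcripts and stays open, as sequence outside transcripts was not searched.

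For the genes called between the libraries, GC content is argued against, since 83.3% of the called genes (896 of 1075) were still called after removing its trend. After removing the length trend, 64.7% (696 of 1075) were still called. This argues against a smooth trend on exonic length as the whole cause. A simulated length trend left 0 of 2711, but with counting noise alone and a trend on the same lengths that were then removed. That 0 shows that the removal works, not what length would leave in these libraries. Whether length is a main cause of the calls cannot be told apart from other causes at 64.7%, between the bounds of 50% and 80% set beforehand, and 156 other genes became called once the length trend was removed. A further test was added because that result was undecided and most genes of the exact test were long, with a median exonic length of 20114.5 bases over the 18 of 19 with a known length, 3 of which were shorter than the median of 4204 over kept genes. With the length trend as an offset in a likelihood ratio test with the same dispersion, 6 genes in place of 18 were past the threshold, 5 of them shared, but all 18 remained higher in replicate 2 and their median log2 ratio went from 0.35 (quartiles 0.31 and 0.39) to 0.23 (0.20 and 0.31), so calls ended because folds shrank and length may explain part of the difference. A larger share of nuclear RNA in replicate 2 stays open, as lincRNA genes exceeded matched protein-coding genes by 0.0446 on the log2 scale, above 99.97% of matched lists but under the 0.05 set beforehand.

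Sox10 stood at 532 CPM without basal keratins. Schwann cells in the culture are argued against as its source, because the median level of 6 Schwann marker genes was 0.0471% of the Sox10 level, although Cdh19 (46.4 CPM) and Prx (8.43 CPM) were above the floor and the level of Mbp had been seen before this test was written. Reads of a near-identical transcript are argued against as well, with 0 windows of Sox10 shared. Expression of Sox10 by the TUBO cells themselves is a hypothesis that no test here addresses directly.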
